A study of Mus musculus with 6 samples.

How the data were processed

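RNA of mouse CD4-positive T cells was sequenced in 6 libraries, 3 from control cells, called vehicle here, and 3 from cells given tunicamycin at 0.15 µg/mL. The sample titles call the cells of all 6 libraries WT and the control cells untreated. Whether the controls received the solvent is not settled by these titles. Per the labels' protocols, cells from spleen and mesenteric lymph node were depleted of regulatory T cells and cultured for 4 h at 1000000 cells per well. Per the labels' protocols, libraries were made from 200 ng of total RNA and sequenced as paired reads of 150 bp. The labels call the 3 libraries of a group technical replicates, so p-values measure only the spread between libraries.

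The submitters' processing notes name bcl2fastq, Salmon, DESeq2 and the genome build GRCm39, without a version or a role. The authors deposited estimated counts per gene, which are partly fractional and not scaled to depth. The authors also deposited TPM values for the same rows. The transcript annotation, and how transcripts were summed to genes, are not given in the sources used here. The table used here held 13685 rows, of which 6932 were at 0 in every library. The deposited TPM values of these rows sum to between 319120 and 332870 per library, so the rows hold a part of the transcriptome. Of 21951 protein-coding genes in the GENCODE M21 annotation of build GRCm38, 8538 had a row. A row was present for 77.2% of protein-coding genes with a single transcript and for 9.2% of those with at least 6 transcripts. The totals below are sums over these rows and not library depths. Gene symbols were matched for 13627 identifiers. Positions are given on GRCm38, the build of the annotation used here, and were not converted to the build of the processing notes.

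Estimated counts, as deposited, were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr on the groups, which left 3613 genes, and libraries were scaled with TMM factors. The main test was the 2-sided quasi-likelihood F test with robust estimation, Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes beyond 1.5 were tested with glmTreat. Intervals are 95% intervals of the fitted log2 fold change, with a median half-width of 0.20 over the 1912 genes with a mean of at least 5 log2 CPM. CPM values use the TMM-scaled library sizes, and log2 CPM uses a prior count of 2. Where a gene had no counts in a group, the fold was bounded against 3 counts per library, which covers counting error only.

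Before the data were examined, 38 gene lists, the test, the alternatives and the rule for naming genes were fixed. Whether the main test should hold a replicate block was decided after the calls of both fits had been seen. Lists with at least 3 tested members, 32 in all, were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry from limma 3.58.1. The rule named up to 10 rises and 10 falls past the threshold with non-overlapping groups and a mean of at least 1 log2 CPM, 8 genes of the response to tunicamycin, and per list up to 4 members past the threshold. Where under 2 members passed, up to 2 further members with the highest mean were named. Genes outside the rule are named as chosen after their values were seen.

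The fit was tested on simulated counts for 3613 genes with the means, dispersions and library sizes of this comparison. Of 50 genes changed 2-fold, 76% were called, and of 50 changed 1.5-fold, 32%. Among genes with a mean of at least 5 log2 CPM, 100% of 37 changed 2-fold and 71.4% of 21 changed 1.5-fold were called. In the same simulation, 50 genes each were also changed 1.25-fold and 4-fold. With so many changed genes the adjustment is milder than in the data, where 3 genes passed. These percentages can therefore overstate the power in the data. Among the unchanged genes, 5 were called. Alternatives were other scalings, other filters, DESeq2 1.42.0, limma on log2(TPM + 1) and log2(TPM + 0.1), leaving out the 20 genes with the most counts, leaving out each library, a replicate block and a fit without robust estimation. Offsets for effective length and GC content, library sizes from the count-to-TPM ratio, and leaving out pseudogene, immunoglobulin and T cell receptor rows were added after seeing the data.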

Results

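Transcript levels were measured by RNA sequencing in WT mouse CD4-positive T cells from spleen and mesenteric lymph node. The cells were cultured for 4 h with tunicamycin or as controls, called vehicle here and titled as untreated. Tunicamycin inhibits the first step of N-linked glycosylation and is used to induce the unfolded protein response. There were 3 libraries per group. The summed counts of the rows analysed were 7412151, 7618385 and 9495725 in vehicle replicates 1 to 3 and 10584276, 11211270 and 10868816 in tunicamycin replicates 1 to 3. The labels call the libraries of a group technical replicates, so the p-values measure only the spread between libraries. The chi-square per degree of freedom between libraries of a group was 15.8 to 36.1 over genes, so none agreed within sampling noise. Mitochondrially encoded transcripts made up 17.3% ± 1.14 (SD, n = 3) of vehicle counts and 16.9% ± 1.33 (SD, n = 3) of tunicamycin counts. These are shares of the rows analysed, a part of the transcriptome, and not of whole libraries.

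The comparison of tunicamycin with vehicle asks how gene expression responds to exposure to tunicamycin, which is used to induce the unfolded protein response. Of 3613 genes tested, 2 were higher and 1 was lower in tunicamycin in the main fit, which has no replicate block. Rps12l1 (ENSMUSG00000078087), annotated as a processed pseudogene related to the ribosomal protein gene Rps12, had 0 counts in each vehicle library and 214 ± 32.9 CPM (SD, n = 3) in tunicamycin, at least 568-fold higher (edgeR adjusted p = 2.5e-08). Nnt (ENSMUSG00000116207), a mitochondrial transhydrogenase gene, had 0 counts in each vehicle library and 28.1 ± 12.8 CPM (SD, n = 3) in tunicamycin, at least 74.7-fold higher (edgeR adjusted p = 0.0035). Ccng1 (ENSMUSG00000020326), which encodes cyclin G1 and is a transcriptional target of p53, fell from 972 ± 32.2 to 744 ± 40.6 CPM (SD, n = 3 each), a log2 fold change of -0.39 with an SE of 0.06 (edgeR adjusted p = 0.025).

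On GRCm38, Rps12l1 lies on chromosome 7 from 56014016 to 56014414, Nnt on chromosome 13 from 119335528 to 119408952, and Ccng1 on chromosome 11 from 40748552 to 40755311. Reads of a pseudogene and its parent gene, or of overlapping gene models, can be split by the counting, so the values of Rps12l1 and Nnt are uncertain. The 2 higher genes also passed the test against a 1.5-fold change, and 0 lower genes did (edgeR glmTreat), with 115 genes lower at an unadjusted p under 0.05 in the test of any change. DESeq2 called 10 genes higher and 12 lower, edgeR with DESeq2 size factors 2 and 2, edgeR without a composition factor 2 and 0, and limma on log2(TPM + 1) 1 and 0. With a replicate block, edgeR called 14 genes higher and 22 lower. Among them, named after their values were seen, were Pck2 higher and Fbl and Rpl35 lower. With the block and effective-length offsets 3 were higher and 3 lower, and none of these named genes passed. Whether the replicate numbers pair the libraries is not settled. In the main fit, 232 genes had an unadjusted p under 0.05, against 181 expected by chance. With the replicate block 387 genes had an unadjusted p under 0.05, and with the block and effective-length offsets 364. The groups did not overlap for 12.6% of genes, against 10% by chance. The call of Ccng1 was lost without vehicle replicate 1, 2 or 3 (edgeR adjusted p = 0.27, 0.089 and 0.055) and without tunicamycin replicate 2 or 3 (edgeR adjusted p = 0.34 and 0.28), with a range of 5.3e-07 to 0.42 over all alternatives. The call of Nnt was lost without vehicle replicate 2 (edgeR adjusted p = 0.089, with a range of 4.1e-13 to 0.42 over all alternatives), which left 1 gene called higher, and without vehicle replicate 3 there were 4.

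**Figure D1:**
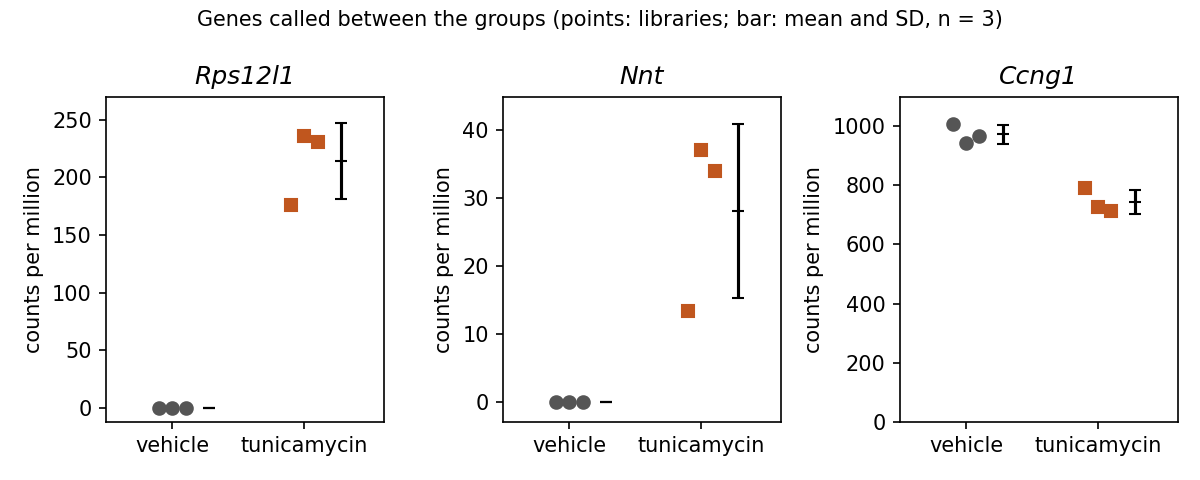
Normalised CPM of Rps12l1, Nnt and Ccng1 by group, with each library as a point and the mean with its SD (n = 3) beside it. Rps12l1 and Nnt sit at 0 in each vehicle library, and Ccng1 is lower in each tunicamycin library than in any vehicle library.

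Of 3 tested sensors and transcription factors of the unfolded protein response, 0 passed the threshold. Over the 36 fixed lists that had a tested member and none called by edgeR, 31 of 230 genes had an unadjusted p under 0.05, DESeq2 called 0 higher and 4 lower, and limma on log2(TPM + 1) called 0. The 4, named after their values were seen, were Fbl, Rps23, Rpl35 and Rpl23, so 0 by edgeR in the groups that follow was 0 by DESeq2 and limma except where given. Atf4, a transcription factor of the integrated stress response, had a log2 fold change of -0.05 (95% interval -0.19 to 0.10). Atf6, a sensor of endoplasmic reticulum stress, was at -0.01 (95% interval -0.45 to 0.42). Dpagt1, which encodes the enzyme that tunicamycin inhibits, was at 0.18 (95% interval -0.18 to 0.55). Hspa5, Ddit3, Xbp1, Ern1 and Eif2ak3 were not analysed here. Of 8 chaperone and folding genes tested, 0 passed over all genes or adjusted over the list alone in edgeR, and 1 had an unadjusted p under 0.05. Calr, the chaperone calreticulin, was at -0.14 (95% interval -0.25 to -0.03), and Ppib was at -0.12 (95% interval -0.25 to 0.02). Dnajb9 and Dnajc3, chosen after their values were seen, were at 0.05 (95% interval -0.14 to 0.24) and 0.01 (95% interval -0.13 to 0.15). Of 6 genes of degradation from the endoplasmic reticulum, 0 passed, and Vcp was at -0.12 (95% interval -0.24 to 0.00). Of 5 stress response targets, 0 passed, and Ddit4 and Sesn2 were at -0.01 (95% interval -0.21 to 0.20) and 0.02 (95% interval -0.23 to 0.26). Over the sensor, chaperone, degradation and stress response lists, the upper 95% bound lay under a 2-fold rise for 20 of 22 tested genes. The exceptions, Derl3 and Stc2, had few counts and are named after their values were seen. For 17 of 17 genes with a mean of at least 5 log2 CPM the bound lay under a 2-fold rise.

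**Figure D2:**
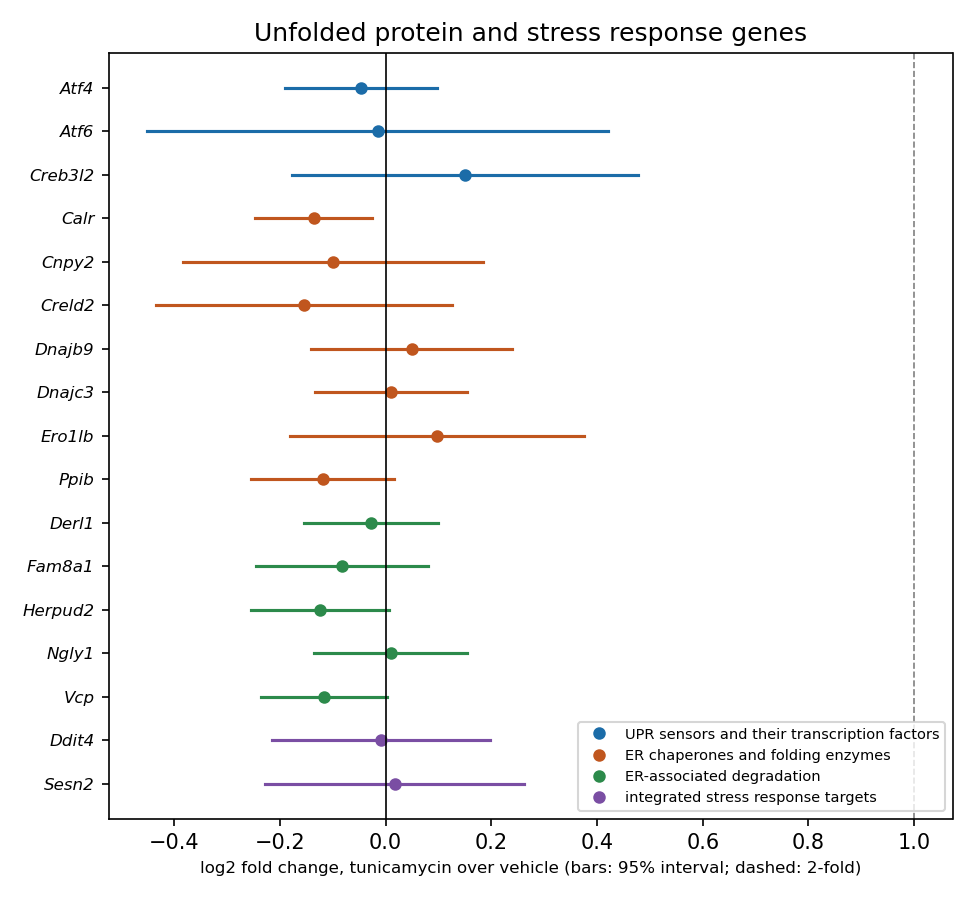
Log2 fold change of tunicamycin over vehicle for the 17 tested genes of these 4 lists with a mean of at least 5 log2 CPM, with 95% intervals as bars and colours for the lists. The dashed line marks a 2-fold rise, which lies above each interval.

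Among genes of amino acid synthesis and transport, 0 of 5 passed over all genes and 1 passed adjusted over the list alone. This was Pck2, the mitochondrial phosphoenolpyruvate carboxykinase, at 0.37 with an SE of 0.09 (edgeR adjusted p = 0.36 over all genes), chosen after its values were seen. In edgeR, Pck2 was called higher over all genes without the filter on low counts and with the replicate block. It was not called with the block and effective-length offsets, or by DESeq2. Of 11 genes of N-linked glycosylation, 0 passed in edgeR, and 2 had an unadjusted p under 0.05. Ganab was at 0.14 (95% interval 0.02 to 0.25) and Dad1 at -0.17 (95% interval -0.30 to -0.04). Of 13 early activation genes, 0 passed, and Junb and Jund were at 0.02 (95% interval -0.28 to 0.31) and -0.02 (95% interval -0.13 to 0.09). Of 8 genes of naive and quiescent T cells, 0 passed, and Il7r, the receptor of interleukin 7, had a 95% interval of -0.15 to 0.15. Of 7 T cell receptor genes, 0 passed in edgeR, and Cd3e was at -0.13 (95% interval -0.25 to -0.01). Of 7 cytokine genes, 0 passed, and Cd40lg was at 0.04 (95% interval -0.17 to 0.25). Of 27 nuclear-encoded respiratory chain genes, 0 passed, with a median of -0.02. The lists of cell death genes, heat shock proteins, NRF2 targets and cholesterol synthesis had 0 members past the threshold and medians of -0.08, -0.02, -0.10 and -0.06. Interferon response, cell cycle, regulatory T cell and T helper genes had 0 members past the threshold and medians of 0.15, 0.04, 0.16 and -0.01. Signal peptide targeting, transport from the endoplasmic reticulum to the Golgi, aminoacyl-tRNA synthetases and autophagy had 0 members past the threshold and medians of -0.12, -0.02, 0.01 and -0.05. With the preset correlation the signal peptide list was called lower with effective-length offsets, chosen after seeing the data, at a median of -0.36 (camera adjusted p = 0.00085), and with limma on log2(TPM + 1) at -0.30 (camera adjusted p = 0.0077). Its adjusted p ran from 0.00028 to 0.93 over all alternatives, the last with an estimated correlation. The medians of the other 3, and of the naive and T cell receptor lists, changed sign in limma on log2(TPM + 1).

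As sets, 4 of 32 lists lay lower in tunicamycin than the other genes by camera with a preset correlation. Of 4 p53 targets tested, 1 fell over all genes and 2 adjusted over the list alone, Ccng1 and Phlda3, with a list median of -0.35 (camera adjusted p = 0.0042). For this list the camera adjusted p = 0.93 with an estimated correlation, here 0.43, so the call was lost (unadjusted camera p = 0.063). Of 3 ribosome biogenesis genes, 0 passed over all genes and 2 fell adjusted over the list alone. These were Fbl, the methyltransferase fibrillarin, at -0.33 (edgeR adjusted p = 0.055) and Rrs1 at -0.34, while Utp20 was at 0.04 (camera adjusted p = 0.0060 for the list). The call was lost in the test with an estimated correlation (camera adjusted p = 0.81, unadjusted camera p = 0.025). The estimate, -0.05, lay below the preset 0.01, so this loss cannot be put down to a higher correlation between these genes. Fbl was also called lower by DESeq2. Of 22 cytosolic ribosomal protein genes, 0 passed over all genes in edgeR, 3 fell in DESeq2 and 2 fell adjusted over the list alone, with a median of -0.08 (camera adjusted p = 0.0060). The call was lost with an estimated correlation (camera adjusted p = 0.93). Rpl35 was at -0.28 with an SE of 0.06 (edgeR adjusted p = 0.23). Phlda3, Fbl, Rrs1 and Rpl35 were chosen after their values were seen. Of 13 mitochondrially encoded transcripts, 0 passed in edgeR and 6 had an unadjusted p under 0.05, with a median of -0.11 (camera adjusted p = 0.037). The call was lost with an estimated correlation (camera adjusted p = 0.93). The transcript mt-Nd6, chosen after its values were seen, was at 0.51. By fry, which tests whether the genes of a list move one way on balance, ribosome biogenesis alone passed (fry adjusted p = 0.016). Without vehicle replicate 3 or tunicamycin replicate 2 the ribosomal protein list was not called (camera adjusted p = 0.70 and 0.14), nor the mitochondrially encoded list without vehicle replicate 2 or tunicamycin replicate 3 (camera adjusted p = 0.49 and 0.55). The sensor list had a median below 0 and a camera direction up, and the aminoacyl-tRNA synthetase, plasma cell and macrophage lists had a median above 0 and a camera direction down, none of them called. The same test called up to 7 lists in other splits of the 6 libraries, and 6 of the 10 splits, the real one included, called at least 4.

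Markers of other cell types were also compared. All 5 tested NK cell markers had a log2 fold change above 0, with a median of 1.11, and the list missed the threshold (camera adjusted p = 0.051). The mean log2 deviation of its members was -0.85, -0.67 and 0.04 in vehicle replicates 1, 2 and 3. In tunicamycin replicates 1, 2 and 3 it was 0.63, 0.77 and 0.09, so the libraries numbered 3 hardly differed. The list passed without vehicle replicate 1, vehicle replicate 3 or tunicamycin replicate 3 (camera adjusted p = 0.034, 0.019 and 0.0019), all with the preset correlation. With an estimated correlation its adjusted p = 0.93, and by fry its adjusted p = 0.33. Gzma, the protease granzyme A, was at 1.15 (95% interval 0.17 to 2.13) with a mean of 2.81 log2 CPM. Prf1, the only tested member with a mean of at least 5 log2 CPM, was at 0.02 (95% interval -0.23 to 0.26). Of 5 plasma cell markers, 0 passed. Igha, the constant region of IgA, was at 77.8, 152 and 18.6 TPM in vehicle replicates 1, 2 and 3, and at 86.8, 160 and 21.5 TPM in tunicamycin replicates 1, 2 and 3. Its log2 fold change was 0.06 (95% interval -2.85 to 2.98). Of 3 B cell markers, 0 passed, and Cd79a was at -0.35 (95% interval -1.26 to 0.56). Of 4 macrophage markers, 0 passed, and Lyz2 was at 0.15 (95% interval -1.03 to 1.32). Of 7 erythroid and platelet markers, 0 passed, with a median of -0.35. Of 2 neutrophil markers, 1 dendritic cell marker and 1 CD8 T cell marker tested, 0 passed, and no stromal or endothelial marker was tested. Of 2 glycolysis genes and 2 reported targets of regulated RNA decay by IRE1, 0 passed.

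**Figure D3:**
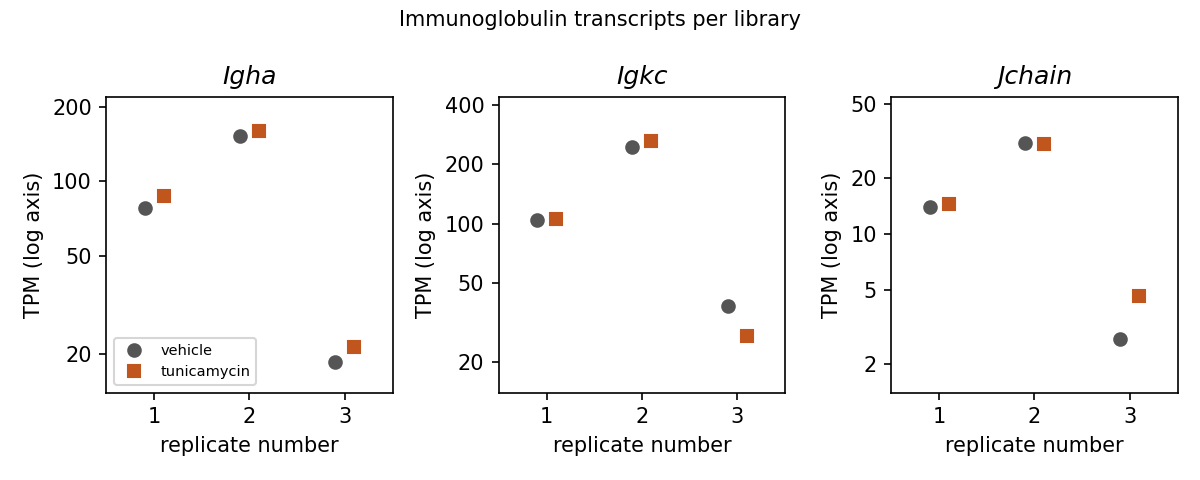
Igha, Igkc and Jchain in TPM on a log axis by replicate number, with vehicle as circles and tunicamycin as squares. Replicate 2 is the highest and replicate 3 the lowest in both groups for each of the 3 genes.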

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

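All tests of the patterns below were chosen after the result was seen, except those of reads shared with Rps12, of transcript sets and of the splits of the libraries.

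A difference between the groups appeared in the ratio of deposited count to TPM, which no planned comparison used. Over 261 genes with a GC content of at least 57.9%, the median log2 deviation of this ratio was 0.043 ± 0.007 in vehicle and -0.036 ± 0.002 in tunicamycin (SD, n = 3 each), a difference of -0.079 (exact permutation test, p = 0.1, the smallest the design allows).

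The sensor, chaperone, degradation and stress response lists of the unfolded protein response showed no called rise. The amino acid list, where Pck2 was called in some alternatives, is not part of this summary. Too little depth to see a 2-fold rise is argued against for most members that passed the filter on low counts, since 90.9% of them had an upper 95% bound under it. It cannot speak for members that the filter removed. Of the chaperones 9 had a row and 8 were tested, and of the stress response targets 9 had a row and 5 were tested. A smaller rise is not excluded, and the intervals measure only the spread between libraries. The tested members were 3 of 11 listed sensors and transcription factors, 8 of 28 chaperones, 6 of 24 degradation genes and 5 of 21 stress response targets. A mislabelled library stays open: the bound set for it was a range under 0.58 log2 over the libraries, and the stress response list had 0.774, within the vehicle libraries, where Stc2 had 4, 45 and 6 counts, while the chaperone list had 0.167. A response in genes not analysed here also stays open, since 5 of the 8 genes fixed beforehand were not analysed. A weak biological response at this dose and time was not tested.

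Rps12l1 and Nnt were at 0 in every vehicle library. Lower depth is argued against, since at the tunicamycin level of Nnt at least 209 counts would be expected in each vehicle library. A wide difference in the transcript sets quantified is argued against by the number of genes. Only 2 were at 0 in 1 group and at 10 or more counts in each library of the other. Other splits gave up to 2, but at lower counts. The smallest tunicamycin count was 1878 for Rps12l1 and 143 for Nnt. For genes of other splits the smallest count in the group above 0 was at most 116. A difference limited to these gene models is not excluded. Reads shared with Rps12 stay open, since Rps12 differed by -133 CPM with an SE of 214, as wide as the 214 CPM of Rps12l1. Reads shared with another Nnt model stay open, since 1 Nnt model was analysed. A strain or donor variant cannot be told apart from the treatment, since the state differed between the groups in 3 of 3 replicate numbers and the labels give no donors.

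Immunoglobulin transcripts matched by replicate number. Aliquots of 1 cell pool stay open: Igha differed 8.18-fold between vehicle libraries (interval 7.55 to 8.87, for counting error only), and uneven sampling of a few cells between wells was not measured. A candidate explanation is that libraries of the same number share a donor or cell pool: over 70 immunoglobulin V genes, 6 of 6 libraries correlated best with their own number across genes, which are not independent replicates. The correlations with the own number were 0.412, 0.358 and 0.265, and those with other numbers ran from -0.278 to -0.0765. An exact test over the 6 matchings gave p = 0.167, the smallest it allows, so it cannot decide on chance, which stays open.

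The 6 libraries make 10 splits, too few for a share under 0.05. The real split called 2 genes higher and 1 lower, and the highest of the others called 1 in either direction. Splits with as many genes numbered 1 for the higher and 3 for the lower genes. Beyond 1.5-fold, the real split called 2 higher and 0 lower and the highest other 1, with 1 and 10 splits as large. Every split reaches a count of 0, so the comparison for lower genes cannot tell anything. For lists the real split called 4 and the highest other 7, with 6 splits as large.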

How the results depend on the processing

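The added offsets, the ratio-based library sizes and the fit without pseudogene, immunoglobulin and T cell receptor rows were chosen after seeing the data. Rps12l1 was called in all 23 alternatives that tested it, Nnt in 20 of 24 and Ccng1 in 12 of 24, where its log2 fold change ran from -0.43 to -0.34 and its adjusted p from 5.3e-07 to 0.42. The p53 list was called in 24 of 25 alternatives, ribosome biogenesis in 19, cytosolic ribosomal proteins in 17 and mitochondrially encoded transcripts in 16, with camera adjusted p from 0.00047 to 0.93, 0.0018 to 0.81, 3.2e-06 to 0.93 and 0.00067 to 0.93. Over 98 named genes, 2220 of 2331 values kept direction and side of the threshold or moved within 1 SE, 16 lost a call, 25 gained one and 70 changed direction beyond 1 SE without a call. Lists that changed direction, by median or by camera, were never called: 88 values stayed within the spread between replicates and 25 went beyond it. A filter at 1 CPM in 3 libraries left the same 3613 genes and so tests nothing. Depth limits genes with few counts most. The cause of the changes below was not tested.

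Genes called lower numbered 2 with DESeq2 size factors, 0 without a composition factor, 0 without robust estimation, 0 with effective-length offsets and 0 with ratio-based library sizes. Without a filter 10 were higher and 6 lower, and by DESeq2 10 and 12. With limma on TPM 1 was higher and 0 lower in each of the 3 settings, and 1 was higher beyond 1.5-fold. Without pseudogene, immunoglobulin and T cell receptor rows, 1 was higher, 2 lower and 1 higher beyond 1.5-fold. Leaving out 1 library gave 1 to 4 genes higher, 0 to 1 lower, 1 to 2 higher beyond 1.5-fold and 0 to 1 lower beyond 1.5-fold. Without vehicle replicate 2, 1 was higher, and without vehicle replicate 3, 4 were. No gene was called lower without vehicle replicates 1 or 2 or tunicamycin replicates 2 or 3.

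Whether the replicate numbers pair the libraries is not settled. The correlations of same-numbered libraries' deviations were 0.04, 0.19 and 0.11 over all tested genes, not all above the bound of 0.1. Every library still correlated best with its own number, a hint from the data. The titles and library names also carry the same numbers in both groups, but the labels call them technical replicates and give no donors. Over the 1912 genes with a mean of at least 5 log2 CPM the same-numbered correlations were 0.324, 0.116 and 0.269, all above the bound. Over the 2481 genes with a mean of at least 3 log2 CPM they were 0.163, 0.335 and 0.158. The block was left out of the main test on the value over all tested genes, after the calls of both fits had been seen. The replicate block called 14 genes higher and 22 lower, among them Pck2, Cxcr6 and Zbtb16 higher and Fbl, Rpl35, Rps23 and mt-Nd3 lower. With the replicate block and effective-length offsets 3 were higher and 3 lower, and of these 7 genes Rps23 alone passed (adjusted p = 0.040). Pck2, Cxcr6, Zbtb16, Fbl, Rpl35 and mt-Nd3 did not (adjusted p = 0.32, 0.21, 0.27, 0.14, 0.39 and 0.72). With the block and GC offsets 16 were higher and 25 lower.

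List medians in log2 follow. With an estimated correlation the calls of p53 targets (-0.35), ribosome biogenesis (-0.33), cytosolic ribosomal proteins (-0.0785) and mitochondrially encoded transcripts (-0.11) were lost. Ribosome biogenesis also lost its call with limma on log2(TPM + 1) with and without a filter (-0.18 each), on log2(TPM + 0.1) (-0.19), with effective-length offsets (-0.26) and with these and the block (-0.25). Cytosolic ribosomal proteins lost theirs with limma on log2(TPM + 1) and log2(TPM + 0.1) (-0.0420 each), without the 20 genes with the most counts (-0.0409), with ratio-based sizes (-0.0285) and with block and effective-length offsets (-0.11), and ranged from -0.12 to -0.0341 with 1 library left out. Mitochondrially encoded transcripts lost theirs without a composition factor (-0.0689), with limma on log2(TPM + 1) with and without a filter (-0.0445 each) and on log2(TPM + 0.1) (-0.0445), without the 20 genes (-0.19) and with ratio-based sizes (-0.0615), and ranged from -0.16 to -0.0170 with 1 library left out. NK cell markers gained a call with DESeq2 size factors (1.104), no filter (1.13), DESeq2 (1.13), limma without a filter (0.38), GC offsets (1.1) and without pseudogene, immunoglobulin and T cell receptor rows (1.105), and ranged from 0.88 to 1.37 with 1 library left out. These calls use the preset correlation, and with an estimated correlation the NK cell list had an adjusted p of 0.93. Signal peptide targeting and translocation gained a call with limma on TPM (-0.30 in each setting), effective-length offsets (-0.36) and these with the block (-0.36).

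Lists that changed direction beyond the spread without a call were these. Transport from the endoplasmic reticulum to the Golgi was at 0.0196 without a composition factor, 0.0131 with limma on log2(TPM + 1) with and without a filter, 0.0135 with log2(TPM + 0.1) and 0.0266 with ratio-based sizes. In the same order, naive T cell genes were at 0.00454, 0.0388, 0.0388 and 0.0118, and T cell receptor genes at 0.00671, 0.0444, 0.0447 and 0.0132. Aminoacyl-tRNA synthetases were at -0.0483 with limma on log2(TPM + 1) with and without a filter, -0.0496 with log2(TPM + 0.1), -0.14 with effective-length offsets, -0.11 with these and the block, and 0.0640 with ratio-based sizes. Autophagy genes were at 0.0322 with limma on log2(TPM + 1) with and without a filter, 0.0324 with log2(TPM + 0.1) and 0.000957 with ratio-based sizes.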

Other observations

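The 3 genes named here were chosen after their values were seen and did not pass the main edgeR test. Zbtb16, a transcription factor of innate-like T cells, was at a log2 fold change of 1.37 (95% interval 0.56 to 2.17, edgeR adjusted p = 0.40). Its groups overlapped, with 8.3, 13.9 and 9.8 CPM in vehicle replicates 1 to 3 and 13.3, 35.9 and 33.3 CPM in tunicamycin replicates 1 to 3. Cxcr6, a chemokine receptor, was at a log2 fold change of 0.99 (95% interval 0.36 to 1.61, edgeR adjusted p = 0.44). It had 34.4 CPM in tunicamycin replicate 1 and 32.1 CPM in vehicle replicate 3. The chemokine gene Ccl5, a member of the cytokine list, was at a log2 fold change of 0.40 (95% interval 0.08 to 0.72, edgeR adjusted p = 0.61). DESeq2 called Zbtb16 (adjusted p = 0.047) and Cxcr6 (adjusted p = 0.039), and edgeR called Cxcr6 without tunicamycin replicate 1 (adjusted p = 0.044).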
